A study of Mus musculus with 6 samples.

How the data were processed

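RNA of the cochlea of mice at postnatal day 7 was sequenced in 6 libraries, 3 labelled Neu4 knockout and 3 wild type. Per the labels' protocols, libraries were made with the VAHTS Universal V6 kit for Illumina sequencing. The authors deposited 1 table of FPKM values, 1 column per library, with the gene identifier, symbol, biotype and position. Genome build GRCm38 is given per the submitters' processing notes, and the aligner, the counting tool and its strand setting are not given in the sources used here. Each of the 30462 genes was above 0 in at least 1 library, and 0 library pairs held identical values.

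FPKM removes depth. The FPKM of a gene times its exon length (GENCODE M21) was a whole multiple of 1 step per library, within 0.01 fragment plus a relative 1e-06, for 98.3% of the values above 0 in each library, and 29933 genes (98.3%) were whole in all libraries. The steps gave library totals of 15170973 to 17192293 fragments. For Neu4, 1 fragment was worth about 0.0129 FPKM in knockout 2, so that low genes rest on few fragments.

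Genes with an FPKM of at least 1 in at least 3 libraries were tested on log2(FPKM + 1) with limma (lmFit and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Gene lists with at least 4 tested members were tested with camera (limma, preset correlation 0.01), and again with an estimated correlation and with fry. The 46 lists, of which 44 had enough members, hold markers of cell types, neighbouring tissues, pathways and RNA quality. Of the listed genes, 2 were matched by an older symbol and 4 were not matched. The targeted gene was tested by exact permutation. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

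The groups, the lists, the tests, the alternatives named as planned and the rule for named genes were fixed before the data were examined. The rule took Neu4, then up to 12 genes that rose and up to 12 that fell with the largest absolute log2 fold change among called genes whose groups did not overlap, with a mean FPKM of at least 5 in the higher group and no predicted-gene name. From each list it took up to 4 called members or, where none was called, the 2 with the highest mean. Other genes named in the text (Tmem181b-ps, Gm47283, Mid1-ps1, Dynlt1-ps1, and list members such as Ush1c, Slc17a6, Notch3, Lpl and Cd33) were chosen after their values were seen.

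Alternatives were other pseudocounts, filters, scaling, eBayes settings, library weights, sex as a covariate, a replicate block and leaving out each library. Added after seeing the data were voom (limma) on the recovered fragments, protein-coding genes only and a soft tissue component as a covariate. On simulated data for this comparison (5 runs, 200 changed genes, 13830 genes tested in the median run) the limma test recovered 83.4% of genes changed 1.5-fold and 98.6% of those changed 2-fold, with 6.47% false calls. All 5 lists moved by 1.25-fold were called and 0 of the unmoved ones. Simulated genes of a similar level had the same spread, and changed genes were not taken from the lowest levels. The recovered shares therefore do not hold for low genes or for genes that vary widely between libraries. The simulated genes were also drawn independently of each other. In the real data the estimated correlation reached 0.888 (skeletal muscle list), so these runs cannot show how often camera falsely calls correlated lists. The edgeR count test planned for raw counts was not run, since the deposited values are FPKM. Of the tests over all genes, only voom used the recovered fragments.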

Results

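The series compared the cochlea, the hearing organ of the inner ear, of wild-type mice with that of mice labelled as Neu4 mutants at postnatal day 7. Neu4 encodes a sialidase, an enzyme that removes sialic acid from glycoproteins and glycolipids. RNA of 6 samples was sequenced, 3 labelled Neu4 knockout (replicates 2, 4 and 5) and 3 wild type (replicates 3, 4 and 5). The deposited table gave FPKM values for 30462 genes, of which 18070 were protein coding. The library totals implied by the values were between 15170973 (knockout 5) and 17192293 (wild type 4) fragments. In each library 13916 to 14154 genes had an FPKM of at least 1. Mitochondrial genes took 2.28% to 2.56% of fragments, and ribosomal RNA genes took 0.297% to 0.829%, the highest share being that of wild type 5. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples.

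The targeted gene was at the same low level in both groups. Neu4 (ENSMUSG00000034000, chromosome 1, 94020451 to 94028334, plus strand, GRCm38) had an FPKM of 0.0797 ± 0.0255 (SD, n = 3) in the libraries labelled knockout and 0.0779 ± 0.0242 (SD, n = 3) in wild type. These values correspond to 4, 8 and 6 fragments over 4637 bp of exons in knockouts 2, 4 and 5, and to 4, 8 and 6 fragments in wild types 3, 4 and 5. The ratio of fragment rates, knockout over wild type, was 1.02 with a 95% Poisson interval of 0.5001 to 2.08, which covers counting error only. An exact two-sided permutation test gave p = 0.8, the smallest p for 3 against 3 being 0.1. Neu4 RNA therefore did not check the labels, and directions below refer to libraries labelled knockout. The part of the gene changed in the mutant is not given in the labels, and fragments outside it would not check the genotype.

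Xist, the RNA of the inactive X chromosome, and the Y-linked gene Ddx3y gave the sex of each library. Knockout 2 and wild types 3 and 4 were male, with Ddx3y FPKM of 9.48, 7.82 and 8.47. Knockouts 4 and 5 and wild type 5 were female, with Xist FPKM of 24.6, 28.2 and 9.23 and Ddx3y listed at 0. The sexes were thus unequal between the groups. The list of 5 sex-linked genes (camera adjusted p = 0.528) joins Xist with genes of the Y chromosome, which go opposite ways, so that its p says nothing on sex.

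Between the genotypes, 47 of the 14072 genes tested changed, 18 higher and 29 lower in the libraries labelled knockout (limma, Benjamini-Hochberg adjusted p under 0.05). With median-ratio scaling in place of the authors' scaling, the split was 11 higher and 33 lower. The median absolute log2 fold change of the 47 genes was 0.58, and 17 of them (6 higher, 11 lower) had an absolute log2 fold change of at least 1. Of the 47, 32 were protein coding. At an unadjusted p under 0.05 there were 2472 genes, against 703.6 by chance, and their split ran the other way, 1489 higher and 983 lower. The knockout and wild type values did not overlap in 24.8% of the tested genes, where chance gives 10%. Leaving out any single library moved the count by over 1.5 times: to 15 without knockout 2, 16 without knockout 4, 105 without knockout 5, 12 without wild type 3, 12 without wild type 4 and 21 without wild type 5. With sex as a covariate 24 genes were called, 21 of them shared with the 47.

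**Figure D1:**
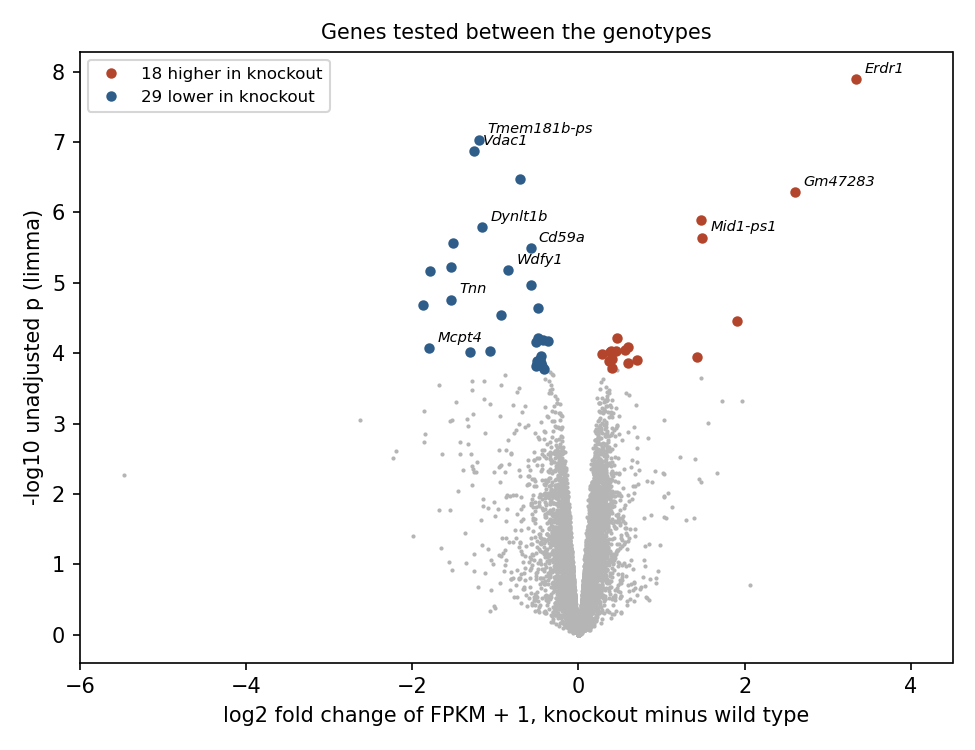
Log2 fold change of FPKM + 1 (knockout minus wild type, x axis) against the negative log10 of the unadjusted limma p (y axis) for the 14072 genes tested. Coloured points are the 18 genes called higher and the 29 called lower, with Erdr1 at 3.34 and Vdac1 at -1.25.

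Erdr1 had the largest increase of any called gene. This long non-coding RNA gene at the distal end of the X chromosome (170009659 to 170019281) had an FPKM of 9.20 ± 1.56 (SD, n = 3) in the libraries labelled knockout and was listed at 0 in all 3 wild type libraries (adjusted p = 0.000181, limma). Of the other genes placed in this part of the sex chromosomes, Gm47283 (chromosome Y, 90784738 to 90816465) rose from a listed 0 to 5.21 ± 1.45 and Mid1-ps1 (chromosome Y, 90753057 to 90763485) from 1.75 ± 0.356 to 6.70 ± 0.619 (n = 3 each). Both were above 0 in the female knockouts as well as in the male one. Reads of these genes can be shared between the ends of the X and Y chromosomes, so that their assignment to one copy is uncertain.

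The other named genes that rose did so by smaller amounts. Calb2, which encodes the calcium-binding protein calretinin of inner ear neurons and hair cells, rose from 12.6 ± 0.954 to 19.7 ± 1.64 FPKM (log2 fold change 0.60, SE 0.076, n = 3, adjusted p = 0.0425, limma). Nox3, the NADPH oxidase needed for otoconia, rose by a log2 of 0.59 (SE 0.081), and Vmo1, a secreted protein gene, by 0.56 (SE 0.071). Esrrb, a nuclear receptor of strial marginal cells, rose from 6.28 ± 0.208 to 8.64 ± 0.385 FPKM (log2 0.40, SE 0.054). Cadm1, an adhesion molecule of the immunoglobulin family, rose from 23.4 ± 0.376 to 31.1 ± 1.87 FPKM (log2 0.40, SE 0.051). The purine synthesis gene Adss (0.47), Yipf5 (0.46) of the Golgi, Igfbp6 (0.40), the splicing kinase gene Clk1 (0.38), the aminopeptidase gene Enpep (0.37) and Actr2 (0.29) of the actin-nucleating complex made up the rest. All 11 had adjusted p between 0.0406 and 0.0495 (limma), and each was called in some and lost in other alternatives. Cadm1 and Enpep overlap predicted antisense genes, and whether the counting used strand is not given in the sources used here.

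Vdac1 was the protein-coding gene with the smallest adjusted p. It encodes a channel of the outer mitochondrial membrane (chromosome 11, 52360860 to 52389397), and its FPKM fell from 91.5 ± 7.99 to 37.7 ± 0.447 (log2 -1.25, SE 0.063, n = 3, adjusted p = 0.000629, limma). The dynein light chain gene Dynlt1b (chromosome 17, 6430112 to 6436296) fell from 19.3 ± 1.40 to 8.14 ± 0.835 FPKM (log2 -1.16, SE 0.082), and the neighbouring pseudogene Tmem181b-ps (6438524 to 6467022) from 11.5 ± 0.615 to 4.43 ± 0.149 (log2 -1.20, SE 0.057). Dynlt1-ps1, a processed pseudogene on chromosome 6, fell by 0.70 on the log2 scale. These 3 genes have near-identical copies, and how the authors' counting divided shared reads is not given in the sources used here. Vdac1 and Dynlt1b kept their call in every alternative run.

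Of the other named genes that fell, Mcpt4, a mast cell protease gene, had the largest change, from 12.4 ± 0.868 to 3.04 ± 1.54 FPKM (log2 -1.80, SE 0.228, n = 3, adjusted p = 0.0425, limma), and Tnn, which encodes the matrix protein tenascin-N, fell from 16.2 ± 0.648 to 5.04 ± 1.51 (log2 -1.54, SE 0.154, adjusted p = 0.0163). Actg2, the smooth muscle actin gene, fell from 8.96 ± 1.69 to 3.72 ± 0.504 (log2 -1.07, SE 0.138). The matrix gene Fbln1 fell by a log2 of 0.51, the membrane trafficking gene Ehd2 by 0.50, the transcription regulator Zfp703 by 0.48, the long non-coding RNA Bvht by 0.50 and the nuclear matrix gene Banp by 0.49. Cd59a, which encodes a complement inhibitor, fell from 10.96 ± 0.266 to 7.02 ± 0.0272 FPKM (log2 -0.58, SE 0.045, adjusted p = 0.00447, limma). Wdfy1 (chromosome 1, 79702262 to 79776143), a gene whose level is known to differ between laboratory strains, fell from 7.35 ± 0.626 to 3.63 ± 0.218 FPKM (log2 -0.85, SE 0.074, adjusted p = 0.00742, limma). Wdfy1 and Mrpl44 overlap on opposite strands. With 1 library left out, 20 of the 24 named genes lost their call at least once, Mcpt4 without any library other than knockout 5 (adjusted p = 0.127 to 0.142, limma) and Wdfy1 without wild type 4 (0.0596).

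**Figure D2:**
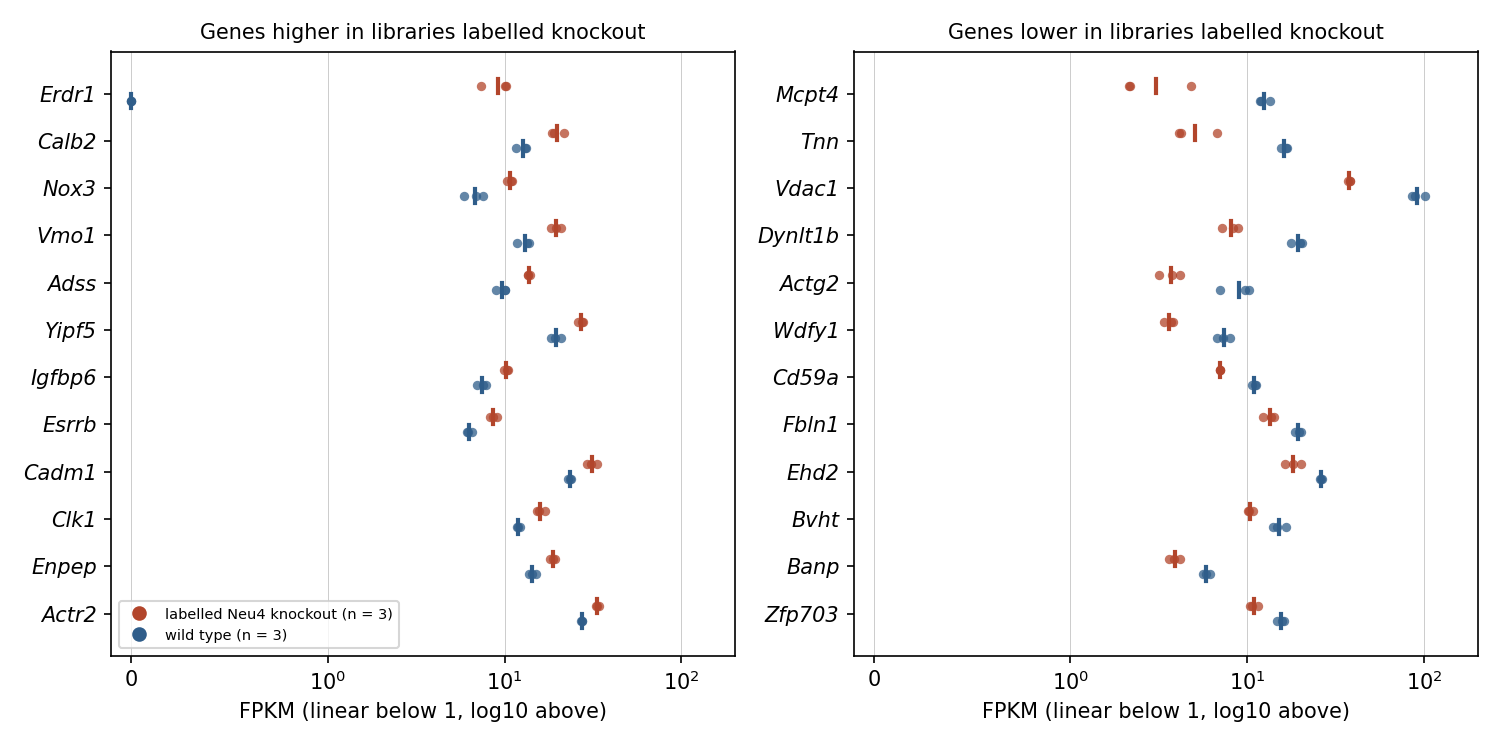
FPKM (x axis, linear below 1 and log10 above) of the 12 named genes higher and the 12 lower in the libraries labelled knockout, with 1 point per library and a bar at the mean of each group (n = 3). Knockout and wild type points do not overlap for any of them, and Erdr1 is at 0 in all wild type libraries.

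Lists of sensory, strial and neuronal genes rose in the libraries labelled knockout by small amounts, as tested by camera with its preset correlation. Of the 44 lists tested, 17 passed, 9 higher and 8 lower. Other splits of the 6 libraries into 3 and 3 called 1 to 20 lists, so a camera call alone does not tie a list to genotype. Among lists that passed, library means overlapped between the groups for tectorial membrane, spiral ganglion neuron, osteoblast, neutrophil, skeletal muscle, immediate early and proliferation genes. Of the 21 hair cell genes tested, 20 were higher (mean log2 0.18, camera adjusted p = 0.00243, and adjusted p = 0.616 with an estimated correlation; 0 changed over all genes, and 2 when adjusted over the list alone), a call lost with genes of FPKM 5 or more (adjusted p = 0.0942). Among them were Ush1c, a scaffold of the stereocilia, at 14.4 ± 1.71 against 10.2 ± 0.623 FPKM, and Myo6, an unconventional myosin, at 9.04 ± 0.190 against 7.54 ± 0.250 (n = 3). The marginal cell list of the stria vascularis, the tissue that makes the potassium-rich endolymph, had 13 of 14 genes higher (mean log2 0.23, adjusted p = 0.000113, and adjusted p = 0.616 with an estimated correlation), with 1 (Esrrb) called over all genes and 8 when adjusted over the list alone. Potassium transport genes were higher in 15 of 18 (mean log2 0.16, adjusted p = 0.000854, and adjusted p = 0.616 with an estimated correlation; 0 over all genes, and 6 when adjusted over the list alone). With an estimated correlation 0 lists passed (1 at an unadjusted p under 0.05), and with fry, whose directional test had 0.0597 as its smallest adjusted p, 0 passed (9 at an unadjusted p under 0.05).

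Other lists of the inner ear rose as well. The tectorial membrane list was higher in 5 of 6 genes (mean log2 0.16, camera adjusted p = 0.0319, and adjusted p = 0.637 with an estimated correlation), with 0 genes changed over all genes and 4 when adjusted over the list alone, and its call was lost without knockout 4 (adjusted p = 0.0997), knockout 5 (0.0956), wild type 3 (0.0687) or wild type 4 (0.0795) and with sex as a covariate (mean log2 0.12, adjusted p = 0.107). Tectb, a protein of that membrane, had 111 ± 9.39 against 95.2 ± 1.21 FPKM, while Tecta had 27.1 ± 5.28 against 27.1 ± 2.81. Intermediate cell genes of the stria were higher in 10 of 13 (mean log2 0.16, adjusted p = 0.0247, and adjusted p = 0.625 with an estimated correlation), with 0 genes over all genes or adjusted over the list alone, and lost its call without knockout 4 (adjusted p = 0.0968), knockout 5 (0.0791) or wild type 5 (0.153) and with genes of FPKM 5 or more (0.150). Spiral ganglion neuron genes were higher in 22 of 27 (mean log2 0.13, adjusted p = 0.0351, and adjusted p = 0.751 with an estimated correlation), with 0 over all genes and 1, Slc17a6, when adjusted over the list alone. This call was lost without knockout 4 (mean log2 0.07, camera adjusted p = 0.460), without wild type 3 (mean log2 0.06, adjusted p = 0.320) with genes of FPKM 5 or more (mean log2 0.04, adjusted p = 0.555), with sex as a covariate (mean log2 0.11, adjusted p = 0.122) and with library weights (mean log2 0.12, adjusted p = 0.0607). The vestibular and otoconia list was higher in 4 of 5 (mean log2 0.20, adjusted p = 0.0446, and adjusted p = 0.616 with an estimated correlation), with 1 (Nox3) called over all genes and 2 when adjusted over the list alone, and lost its call without knockout 4 (adjusted p = 0.168), knockout 5 (0.107), wild type 3 (0.0687) or wild type 4 (0.108), with sex as a covariate (0.204), on ranks (0.157) and without the trend (0.0682). Supporting cell (adjusted p = 0.378), Schwann cell (0.344), spiral ligament fibroblast (0.203), chondrocyte (0.513) and synapse (0.105) lists did not pass camera. Of their genes 0 changed over all genes, and 5, 1, 9, 0 and 0 when adjusted over the list alone. The Schwann cell list passed without wild type 5 (mean log2 -0.22, camera adjusted p = 4.56e-07), the chondrocyte list without knockout 2 (mean log2 0.10, adjusted p = 0.0163), the synapse list without knockout 2 (mean log2 0.15, adjusted p = 0.0250) and on ranks (adjusted p = 0.0468), and the fibroblast list with quantile normalization (adjusted p = 0.0497).

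Lists of markers of tissue around the cochlea also passed camera, and were lower in the libraries labelled knockout. The middle ear epithelium list fell by a mean log2 of 1.35 (median log2 -0.57, 5 of 7 genes lower, camera adjusted p = 0.00931, and adjusted p = 0.616 with an estimated correlation). Its secretory gene Bpifa1, at a log2 of -5.47, weighed heavily on the mean. Bpifa1 had FPKM of 0.0777, 8.34 and 93.3 in knockouts 2, 4 and 5 against 336, 608 and 402 in wild types 3, 4 and 5 (adjusted p = 0.136 over all genes, limma, and 0.0317 with voom, an alternative chosen after seeing the data). Skeletal muscle genes were lower in 14 of 15 (mean log2 -0.93, adjusted p = 0.000786, and adjusted p = 0.663 with an estimated correlation), but the muscle actin gene Acta1 varied widely, at 95.9 ± 70.0 against 183 ± 125 FPKM. The muscle list means overlapped between the groups. They were 3.30, 1.44 and 3.52 in knockouts 2, 4 and 5 and 3.59, 2.93 and 4.52 in wild types 3, 4 and 5. Adipocyte genes were lower in 7 of 8 (mean log2 -0.90, adjusted p = 0.00261, and adjusted p = 0.649 with an estimated correlation). Without knockout 4 the mean log2 was -0.27 for skeletal muscle (adjusted p = 0.0395) and -0.58 for adipocyte genes (adjusted p = 0.00479), and without wild type 5 it was -0.51 for skeletal muscle (adjusted p = 0.0204), each by camera. The counts of genes changed over all genes were 0 for these 3 lists. Adjusted over the list alone they were 4 lower, 0, and 3 lower with 1 higher (Lpl). With the first component of the middle ear epithelium and skeletal muscle lists as a covariate, an alternative chosen after seeing the data, 9 genes and 11 lists were called, 9 of these lists among the 17. This component correlated with the knockout label at -0.623, so a lost call does not show soft tissue to be its cause. The component was lowest in knockout 4 (-1.76) and highest in wild type 5 (1.28), and it takes up part of any genotype difference. The camera calls it ended were those of hair cell (mean log2 0.14, adjusted p = 0.0834), tectorial membrane (mean log2 0.18, adjusted p = 0.0720), intermediate cell (mean log2 0.15, adjusted p = 0.202), spiral ganglion neuron (mean log2 0.03, adjusted p = 0.903), vestibular and otoconia (mean log2 0.21, adjusted p = 0.0720), osteoblast (mean log2 0.12, adjusted p = 0.123), proliferation (mean log2 -0.05, adjusted p = 0.0569) and skeletal muscle genes (mean log2 0.34, adjusted p = 0.0520), and those it added were Schwann cell (mean log2 -0.21, adjusted p = 0.00213) and ribosomal protein genes (mean log2 0.07, adjusted p = 0.0233).

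Matrix and vessel genes were lower. The extracellular matrix list was lower in 16 of 22 (mean log2 -0.21, camera adjusted p = 0.000994, and adjusted p = 0.616 with an estimated correlation). The collagen VI gene Col6a2 fell from 107 ± 3.74 to 82.8 ± 2.73 FPKM (log2 -0.37, SE 0.045, n = 3, adjusted p = 0.0406, limma), the 1 call over all genes, and 10 genes were lower and 1 higher when adjusted over the list alone. Endothelial and pericyte genes were lower in 11 of 16 (mean log2 -0.12, adjusted p = 0.00507, and adjusted p = 0.616 with an estimated correlation), with 0 over all genes and 5 lower and 1 higher when adjusted over the list alone; the call was lost with genes of FPKM 5 or more (adjusted p = 0.0890). Cdh5, the cadherin of endothelial junctions, had 41.5 ± 2.21 against 46.7 ± 1.84 FPKM.

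Of the lists of bone, blood and brain cells, neutrophil and marrow and osteoblast genes passed. The neutrophil and marrow list was higher in 9 of 10 (mean log2 0.87, camera adjusted p = 0.000251, and adjusted p = 0.625 with an estimated correlation), with 0 genes over all genes and 7 when adjusted over the list alone. The granule gene S100a9 had 51.2 ± 14.9 against 19.3 ± 8.40 FPKM, and the list means of the libraries overlapped between the groups. Osteoblast genes were higher in 14 of 16 (mean log2 0.19, adjusted p = 0.00243, and adjusted p = 0.663 with an estimated correlation), with 0 over all genes and 4 when adjusted over the list alone (without knockout 2 the mean log2 was 0.12 and the adjusted p = 0.0553), although Col1a1, the most abundant member, had 3436 ± 559 against 3978 ± 407 FPKM. Osteoclast (adjusted p = 0.805), macrophage (0.967), B cell (0.135), erythroid (0.212) and brain (0.346) lists did not pass camera, with 0 genes changed over all genes and 0, 1, 1, 0 and 0 when adjusted over the list alone. The B cell list passed without knockout 5 (mean log2 0.27, camera adjusted p = 0.0340), without wild type 4 (mean log2 0.30, adjusted p = 0.0377) and with sex as a covariate (mean log2 0.27, adjusted p = 0.0452), and the erythroid list without knockout 2 (mean log2 -0.36, adjusted p = 0.00298) or wild type 5 (mean log2 -0.30, adjusted p = 0.0407). Only 1 of 13 T and natural killer cell genes, Cd4, was tested, and it was 2.23 ± 0.0794 against 2.08 ± 0.166 FPKM.

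**Figure D3:**
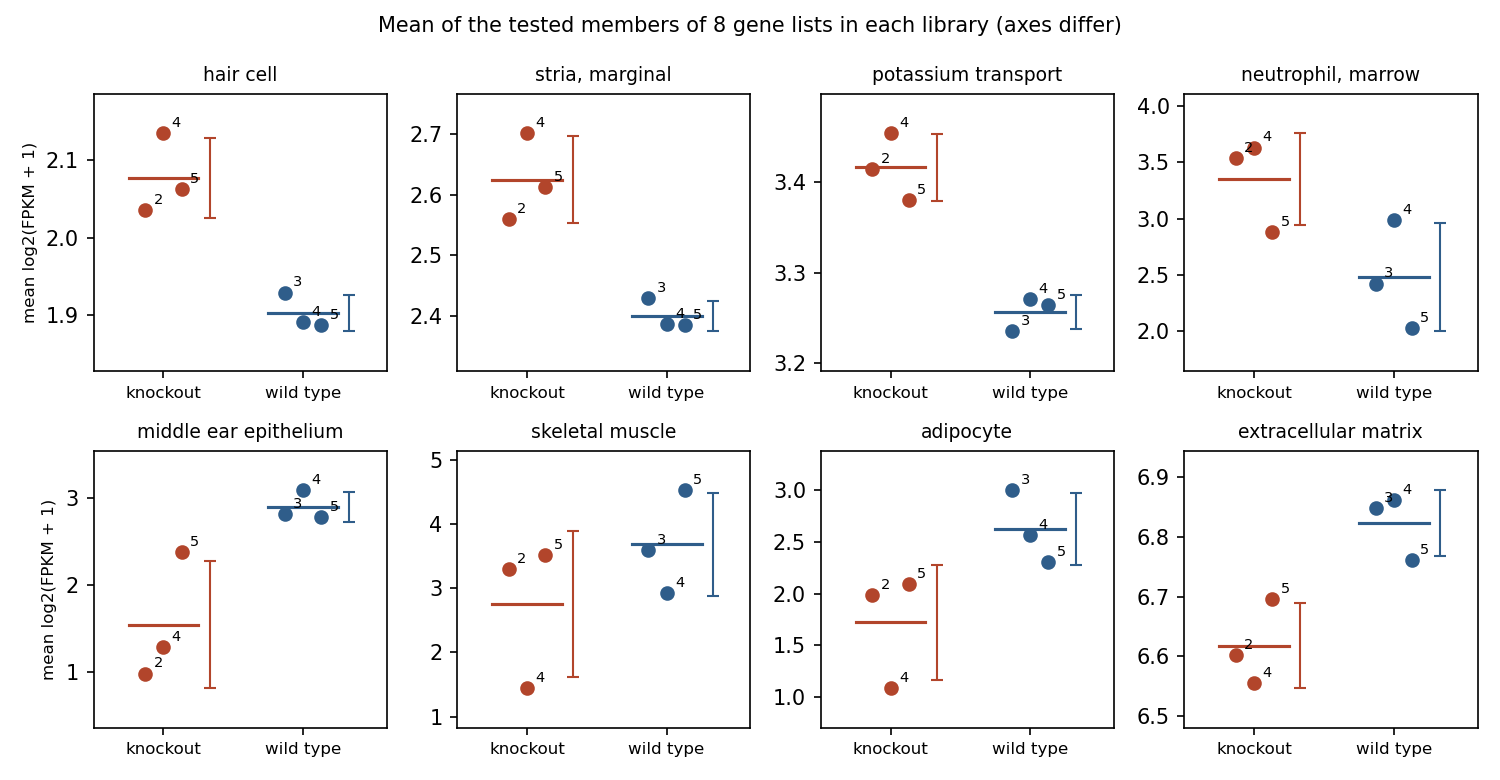
Mean log2(FPKM + 1) of the tested members of 8 gene lists (y axes differ) in each library, with the replicate number beside each point, a bar at the group mean and the SD (n = 3). Middle ear epithelium is at most 2.38 in every library labelled knockout and at least 2.78 in every wild type library, and muscle varies within both groups.

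Genes of sialic acid metabolism did not pass camera as groups. With fry none passed either, but the polysialic acid and ganglioside lists had unadjusted directional p of 0.00318 and 0.00543 (adjusted p = 0.0597 each). Their list means were higher in every library labelled knockout than in any wild type library, by a mean log2 of 0.10 and 0.04. The same held for lists far from passing camera, such as macrophage (0.05) and Neu4 neighbour genes (0.01). Of the 4 polysialic acid genes tested, 2 were higher and 2 lower. Potassium transport genes had a lower unadjusted fry p (0.00202), so the sialic acid lists did not stand out. None of the 5 sialidase-list genes tested changed (camera adjusted p = 0.793): the lysosomal sialidase Neu1 had 13.1 ± 0.825 against 12.9 ± 0.138 FPKM and Neu3, the plasma membrane sialidase, 1.85 ± 0.156 against 1.49 ± 0.172 (n = 3, adjusted p = 0.910 and 0.320, limma). Neu2 was near 0, at 0.0231 ± 0.0232 against 0.0617 ± 0.0350 FPKM. Of 16 genes of sialic acid synthesis and transfer 0 changed (camera adjusted p = 0.916), with St3gal5, the GM3 synthase, at 26.4 ± 1.23 against 23.8 ± 0.567. Of 18 ganglioside genes 0 changed (adjusted p = 0.513), with Psap at 453 ± 22.5 against 450.0 ± 11.9. Of 5 Siglec genes 0 changed (adjusted p = 0.928), and of 30 lysosomal genes 0 changed (adjusted p = 0.967). The 4 tested genes of polysialic acid and its carriers did not pass camera as a list (adjusted p = 0.305), though Cadm1 rose as given above. Ncam1, the main carrier, had 11.3 ± 0.840 against 12.2 ± 1.01. Adjusted over the list alone, the counts were 0, 0, 0, 1 (Cd33), 0 and 2 (Nrp2 and Cadm1).

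Among pathway lists, Notch, proliferation and immediate early genes were lower. Notch genes were lower in 11 of 14 (mean log2 -0.08, camera adjusted p = 0.0247), proliferation genes in 14 of 21 (mean log2 -0.06, adjusted p = 0.0223) and immediate early and stress genes in 11 of 17 (mean log2 -0.09, adjusted p = 0.00243). For each of these 3 the adjusted p = 0.616 with an estimated correlation, 0 genes changed over all genes, and 2, 0 and 6 were lower when adjusted over the list alone. Without 1 library the Notch call was lost (adjusted p = 0.0689 without knockout 5, 0.0852 without wild type 3 and 0.0730 without wild type 4), as was that of proliferation (mean log2 -0.04 and adjusted p = 0.125 without knockout 4, and mean log2 -0.04 and adjusted p = 0.102 without wild type 4). The immediate early list had a mean log2 of -0.05 without knockout 5 (adjusted p = 0.0476). Both were also lost with sex as a covariate (mean log2 -0.07 and -0.04, adjusted p = 0.117 each) and with genes of FPKM 5 or more (adjusted p = 0.0558 and 0.0890). Notch3, a receptor of vascular mural cells, was 11.5 ± 0.187 against 14.1 ± 0.780 FPKM, and Egr1, an immediate early gene, 38.7 ± 2.43 against 47.4 ± 4.81. Immediate early genes also respond to dissection.

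The remaining lists did not pass camera. Adjusted p was 0.903 for Wnt, 0.111 for oxidative phosphorylation, 0.184 for the unfolded protein response and apoptosis, 0.410 for oxidative stress, 0.849 for interferon response, 0.903 for inflammation and 0.170 for cholesterol synthesis. It was 0.702 for mitochondrial genome and 0.902 for ribosomal protein genes, as measures of RNA quality. Oxidative phosphorylation passed without knockout 2 (mean log2 -0.05, adjusted p = 0.0272), wild type 3 (mean log2 -0.06, adjusted p = 0.0408) or wild type 4 (mean log2 -0.03, adjusted p = 0.0489) and with median-ratio scaling (mean log2 -0.06, adjusted p = 0.0367), cholesterol synthesis without wild type 5 (mean log2 0.09, adjusted p = 0.0407), and ribosomal protein genes with quantile normalization (mean log2 0.04, adjusted p = 0.0422), each by camera. None of their genes changed over all genes. Adjusted over the list alone the counts were 4, 0, 1, 1, 0, 3 and 0, and 0 for both quality lists. Ctnnb1, which encodes beta-catenin, had 192 ± 1.66 against 164 ± 2.95 FPKM (adjusted p = 0.0735, limma). Of 13 genes near Neu4 on chromosome 1, 0 changed (list adjusted p = 0.928, and 0 when adjusted over the list alone). Of the 2 strain-variable genes tested Wdfy1 fell, as above, and 1 did not pass. Nnt, a member of that list under the filter, was near 0 in both groups, at 0.0552 ± 0.0269 against 0.0888 ± 0.0350 FPKM. For the osteoclast, lysosome, Wnt, mitochondrial genome, inflammation and Neu4 neighbour lists, the sign of the mean, the median or camera differed.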

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

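The voom, protein-coding and component alternatives were chosen after seeing the data. The count of changed genes (47) was 40 to 56 with the other pseudocounts, median-ratio or quantile scaling and robust shrinkage. It was 19 without a filter, 103 with a filter of FPKM 5, 19 without the trend, 104 with library weights, 24 with sex as a covariate, 17 with an absolute log2 fold change of at least 1, 2472 at an unadjusted p, 337 with voom, 65 with protein-coding genes only and 9 with the component. Leaving out 1 library gave 12 (wild type 3 or wild type 4) to 105 (knockout 5) genes, with 15 without knockout 2, 16 without knockout 4 and 21 without wild type 5. The cause of these moves was not tested. Of the 24 named genes, none turned its sign, and Vdac1, Dynlt1b and Erdr1 kept their call in every alternative that tested them.

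The lists called (17) numbered 9 with the filter of FPKM 5, where hair cell (adjusted p = 0.0942), intermediate cell (0.150), spiral ganglion neuron (0.555), endothelial and pericyte (0.0890), Notch (0.0558) and proliferation (0.0890) lists lost the camera call and 2 had too few genes to test. They numbered 11 with the component (9 of the 17 and 2 others), 13 with sex as a covariate (12 of the 17, without tectorial membrane, spiral ganglion neuron, vestibular and otoconia, Notch and proliferation), 0 with an estimated correlation and 0 with fry, and 12 to 20 when 1 library was left out, 7 of the 17 being lost without at least 1 library. Skeletal muscle turned to a mean log2 of 0.34 with the component, which is built from that list. The log2 fold change of Neu4, 0.0024, changed sign near 0 with library weights (-0.0032), sex (-0.0081), voom (-0.0017) and the component (-0.017), was 0.13 with quantile normalization, the largest move, and ranged from -0.015 to 0.021 when 1 library was left out. None of these passed the threshold.

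The replicate block, the number in the titles, called 22 genes, 9 of them among the 47, and 18 lists, 15 of them among the 17; of the 24 named genes 3 (Erdr1, Vdac1 and Dynlt1b) were called. Only numbers 4 and 5 occur in both genotypes, and no label says what a number marks, so the numbers were not taken as pairs. Deviations from the group means correlated at 0.141 and 0.150 for these 2 pairs and at -0.125 to 0.110 for the 7 pairs with different numbers, 6 of them negative. The edgeR count test planned for a table of raw counts was not run, since the table holds FPKM. Depth limits low genes: Neu4 had 4 to 8 fragments per library.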

Other observations

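All the tests of explanations reported here were chosen after the results were seen, as were the mast cell and epithelial genes named. Besides Mcpt4, 3 other mast cell protease genes were lower in every library labelled knockout: Cpa3 (1.90 ± 0.663 against 5.31 ± 0.825 FPKM), Cma1 (3.01 ± 1.13 against 8.62 ± 1.503) and Tpsb2 (2.37 ± 1.56 against 7.43 ± 0.461; n = 3 each). Their adjusted p were 0.0591, 0.0677 and 0.106 (limma), and 0.0123, 0.0123 and 0.0187 with voom. These 4 genes had been seen to be lower before the list of 12 mast cell genes was written, so their agreement is no independent evidence. Of the other 2 members tested, Kit was 3.83 ± 0.256 against 3.96 ± 0.0619 and Gata2 15.5 ± 0.926 against 13.8 ± 1.02.

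Krt15, Cyp2f2, Pax1 and Eln were picked because they were lower, so their direction is no evidence. None passed on log2 FPKM and all 4 passed with voom (adjusted p = 0.0208, 0.0267, 0.0109 and 0.0151). Krt15 had FPKM of 2.00 ± 2.60 against 10.3 ± 1.56 (adjusted p = 0.123, limma), Cyp2f2, a secretory cell enzyme, 1.41 ± 1.85 against 11.5 ± 3.01 (0.0877) and Pax1, a transcription factor of pharyngeal pouch derivatives, 0.865 ± 0.638 against 4.86 ± 1.496 (0.0640). The elastin gene Eln, a member of the matrix list, had 61.5 ± 38.0 against 204 ± 40.4 (0.0974). With voom, Slc12a2, the sodium-potassium-chloride cotransporter of marginal cells, rose by a log2 of 0.35 (adjusted p = 0.0179), and Sfrp2, a secreted Wnt inhibitor, fell by 0.83 (adjusted p = 0.00741). A limma interaction term of genotype and sex was also fitted. With 1 male knockout and 1 female wild type library, it cannot tell whether the genotype effect differed between the sexes.

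Neu4 was equal in both groups. Of the splits of the 6 libraries, the labelled one called 47 genes and any other at most 6. These counts argue against an exchange of single libraries only if the called genes follow the Neu4 genotype, which was not tested. An exchange of the whole groups would give the same split. An allele that removes all counted fragments would lower the ratio only if the wild type fragments came from Neu4 transcripts. At 4 to 8 fragments per library this could not be tested, so the lower bound of the ratio, 0.5001, does not decide on such an allele. A mutation that leaves most of the transcript in place may account for the equal level, and was not tested.

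The 17 called genes with an absolute log2 fold change of at least 1 included several with near-identical copies. Flanking sequence around Neu4 would place them on chromosome 1, where 3 of the 17 lie. Wdfy1, which is outside this set, lies 14.3 Mb from Neu4, the nearest called gene, and stays open. Sex of the libraries is argued against by the median ratio of their fold changes with and without sex as a covariate, 1.01. Reads moved among the summed copies are argued against for Dynlt1b and Tmem181b-ps alone. The summed fragments of the Dynlt1 and Tmem181 families differed by log2 -0.57 and -0.45. Reads left out of the counts or given to other copies would lower these sums too, and stay open. Moved reads also stay open for others such as Erdr1, Gm47283 and Mid1-ps1. Copy number or background strain that differs between the lines apart from Neu4 may account for the 17 genes, which no DNA was analysed to test. With the soft tissue component as a covariate, 8 of the 17 kept their call. A differing share of soft tissue stays open for the rest. A change caused by the genotype stays open too.

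Muscle, fat and middle ear epithelium lists were lower. If the knockout samples held a smaller share of soft tissue, the muscle, fat, matrix and vessel genes would be less low in knockout 5, the knockout with most middle ear epithelium. Of 61 such genes 38 (62.3%) were higher there than in the mean of knockouts 2 and 4, which does not decide for or against that explanation. Among the knockouts, the list mean of knockout 5 was highest for muscle (3.52), adipocyte (2.09) and matrix genes (6.70) and lowest for vessel genes (3.63). The comparison rests on 1 library, so that dissection and genotype cannot be told apart. A smaller share of soft tissue as the whole cause would raise neutrophil and hair cell genes alike: the neutrophil list exceeded the hair cell list by log2 0.70 (standard error 0.359 over libraries), which leaves this open. Real differences of these tissues with genotype were not tested.

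With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 of 10, the labelled one, called 47, and the highest other called 6. For lists, the other splits called 14, 8, 9, 1, 1, 10, 20, 9 and 10, so camera with its preset correlation called lists in every split. Of the 10 splits, 2 shifted as many lists as the labelled one (17), itself included. The highest, 20, was the split of knockout 2 and wild types 3 and 4 from the rest, which parts males from females. With sex as a covariate 13 lists were called.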
